A study of Mus musculus with 4 samples.

How the data were processed

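The series measured gene expression on 4 Affymetrix mouse arrays. Each array held RNA from leukemic blasts that carried a GFP reporter from the retrovirus used for insertional mutagenesis and that were sorted as GFP-positive, per the labels. The leukemia arose from fetal progenitors with a mutant Gata1, and the cells came directly from mice without culture. Blasts of peripheral blood and of spleen were taken from each of 2 mice, which gave 2 arrays per tissue. Both mice carry the same leukemia designation in the labels, and the spread between replicates is that between these 2 animals. The p-values of single genes measure no more than that. Those of gene lists at a preset correlation, and of tests that shuffle genes, compare genes with other genes. They do not measure agreement between animals. Total RNA was extracted with Trizol and cleaned on columns, and biotinylated cRNA was made by the standard Affymetrix protocol, per the labels' protocols.

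The deposited values are probe set intensities on a linear scale, as the values themselves show. How the authors summarised the probes, subtracted background and scaled the arrays is not given in the sources used here. The 4 array medians lay between 103.7 and 110.6, and between 1.60% and 2.17% of the values of an array were below 0. The deposited scaling was kept. Values below 0 were set to 0, 16 was added and the log2 was taken. The floor at 0 was added to the planned transformation, log2(value + 16), because negative values occur. A fold change is on the log2(value + 16) scale, which understates the change of dim genes. The number of arrays limits the precision of every value.

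Of the 45101 probe sets, 34945 were paired with 1 gene symbol in the platform annotation, 932 with several and 9211 were not listed there. Control probe sets, 64 in number, named no gene. Symbols were updated through the Entrez identifier with a RefSeq gene table of mouse assembly GRCm38.p6, used for names only, which held 34741 of the one-gene probe sets. Each of the 18193 genes was represented by its probe set with the highest mean over the 4 arrays. The 11614 genes whose mean reached the median of all probe sets, an intensity of 106, were tested. No coordinates are given because the array table names no genome build.

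Spleen was compared with blood with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3 with tissue as the sole term, and p-values were adjusted by the Benjamini-Hochberg method at a threshold of 0.05. Errors of log2 differences are standard errors of this fit, and errors of array values are SDs. Gene lists were tested with limma's camera at a preset correlation of 0.01, adjusted over the 22 lists, with an estimated correlation and with fry as alternatives. The lists held 732 genes, and were fixed before the data were examined together with the tests, the filters and the rule for named genes. Within a list, p-values were also adjusted over the list alone, with no correction over the 22 lists. A gene said to rise or fall passed that adjustment only and did not pass over all genes. One further count took genes that differed at least 2-fold the same way in both mice. Another took genes that differed at least 2-fold between the mice in both tissues, with no p-value because each side holds 1 animal. The planned crossed split, with spleen of one mouse and blood of the other on each side, gave the number of genes that differed at least 2-fold in opposite directions in the mice. Camera was also run on this split, which holds no tissue difference shared by the mice.

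Mouse number pairs the arrays because the labels give the same animal for both tissues. Across genes, the difference between the mice in blood correlated with that in spleen at r = 0.10; genes are not independent replicates. The fit with mouse as a block was an alternative. Named genes were, by the fixed rule, the 12 higher and 12 lower genes with the largest smaller within-mouse difference of the same direction, the leading 3 members of each list by the same measure, a set of genes given for their level, and the 8 higher and 8 lower genes for the mice. Other members of a list are named as examples of its count. Other probe sets of a gene can disagree: of the genes named for a difference, Ahnak had 2 of 4 probe sets with the direction of the one used, Fhl1 1 of 2, Pik3c2a 2 of 3, and Mgll 1 of 4. Some genes of the set for levels are not reported here.

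The tests were checked on simulated data for the comparison of spleen and blood, with 11614 genes, the fitted spread and 200 changed genes in each of 10 runs. Of genes changed 2-fold, 74.8% were recovered, and of those changed 4-fold, 97.9%. Of the calls, 5.83% were wrong. Every planted change was equal in both spleen arrays, and the 4-fold genes ease the adjusted threshold for the others. On the measured arrays 2 genes differed at least 3-fold the same way in both mice. The shares recovered therefore need not hold for the measured arrays. A list of mitosis genes shifted by 0.5 on the log2 scale was called in 10 of 10 runs and 0 of 210 tests of the other lists were called. The simulated genes varied independently, which real genes need not do, so the count of 0 says little about calls of lists in real data. On the measured arrays camera called 7 lists on the crossed split. The alternatives were quantile normalization, centring of each array on its median, no filter and a stricter one at the 75th percentile, the mean of all probe sets of a gene, offsets of 1 and 64, a prior with an intensity trend, a robust prior, the fit without eBayes, mouse as a block, fold thresholds of 1.5 and 3, and each array left out in turn. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.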

Results

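The arrays described sorted blasts of a megakaryoblastic leukemia in mice at 2 sites, blood and spleen, with 2 animals each. The 4 arrays were alike in brightness, with median intensities of 110.6 and 108.3 in blood and spleen of mouse 1 and of 108.8 and 103.7 in mouse 2. Ratios of 3' to 5' signal, a sign of RNA integrity, lay between 1.20 and 1.26 for the actin control and between 0.91 and 1.01 for the Gapdh control. The log2 values of the tested genes correlated at r = 0.98 between the tissues of mouse 1 and at r = 0.96 between those of mouse 2, across genes, which are not independent replicates. Pairs of arrays across the mice lay between r = 0.97 and r = 0.98, so the 2 arrays of mouse 2 correlated least.

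The cells carried high levels of genes of the megakaryocyte lineage. The intensity of Pf4, the platelet factor stored in platelet granules, was 8074 ± 534 (SD, n = 4 arrays), that of Itga2b, the platelet integrin chain, was 4496 ± 353, and that of Gp9, part of the von Willebrand factor receptor, was 2035 ± 160. The transcription factor Gata1 stood at 3103 ± 344, Fli1 at 1549 ± 186, Runx1 at 1384 ± 118, Gata2 at 1519 ± 191 and the erythroid factor Klf1 at 1943 ± 137. The place of the Gata1 probe set relative to the mutation is not known here, so its level checks nothing about the mutant. Myc stood at 2802 ± 154, the leukocyte antigen Ptprc at 4516 ± 568, the growth factor receptor Igf1r at 1341 ± 105 and the RNA-binding protein Igf2bp3 at 338 ± 29.9. Cd34, a stem cell antigen, was near 0 on every array, between -3.41 and 0.88. Mpo, a granule enzyme of myeloid cells, was at 144 ± 13.3 and the T cell gene Cd3e at 222 ± 51.2. Probes differ in brightness, so levels of different genes are not ranked here.

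The first comparison asked how blasts in the spleen differed from those in the blood. Genes of mitosis were higher in spleen, and genes of the immediate early response, the fast transcriptional answer of cells to stimuli, were lower. Genes of DNA replication and of megakaryocytes and platelets were also higher in spleen, by smaller amounts. No single gene passed the test over all genes. With limma, 0 of 11614 genes had an adjusted p under the threshold, the smallest adjusted p was 0.140, and 1443 genes had an unadjusted p under 0.05, 943 of them higher and 500 lower in spleen, where chance gives 580.7. The excess of higher genes depended on the processing: quantile normalization gave 765 higher and 602 lower, centred arrays 1310 and 354, and leaving out spleen replicate 1 gave 768 and 772. Fitting mouse as a block also gave 0 genes. A prior with an intensity trend gave 45 genes, 23 higher and 22 lower, and the stricter brightness filter gave 40. These lay just under the threshold: the adjusted p of the 45 ran from 0.040 to 0.049, and the smallest under the stricter filter was 0.046. Leaving out spleen replicate 1 gave 20 genes.

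All 39 tested mitosis genes were higher in spleen in both mice, with a median log2 difference of 0.69 in mouse 1 and 0.75 in mouse 2. Adjusted over the list alone, 36 rose and 3 did not pass, while 0 passed over all genes. Aurka, a spindle kinase, rose by 1.17 ± 0.15 (SE, 2 arrays per tissue), the spindle protein Nusap1 by 1.17 ± 0.13, the spindle motor Kif11 by 1.10 ± 0.14 and the checkpoint kinase Bub1 by 1.05 ± 0.14. With the mean of all probe sets of a gene, Nusap1 differed by 0.64 and Bub1 by 0.70. Camera called the list at an adjusted p of 1.8e-34 with the preset correlation. The call was lost at an adjusted p = 0.557 with an estimated correlation. The adjustment gave this same value to all 11 called lists, so it does not rank them. Before adjustment, camera with an estimated correlation gave p = 0.066 for mitosis and p = 0.31 for granulocytes.

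Of 40 tested genes of DNA replication and E2F targets, 35 were higher in both mice, and the median difference was 0.31. Adjusted over the list alone, 12 rose, among them Ccne2, a cyclin of S phase entry, by 0.64 ± 0.12, the replication licensing factor Cdc6 by 0.63 ± 0.11 and Rrm1, a subunit of ribonucleotide reductase, by 0.60 ± 0.12. That count was 0 without blood replicate 1, without blood replicate 2 and without spleen replicate 2. The list was called at an adjusted p of 3.5e-10, with an adjusted p = 0.557 with an estimated correlation.

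Megakaryocyte and platelet genes were higher in spleen in both mice for 17 of 23 tested members, with a median difference of 0.27. Adjusted over the list alone, 4 rose: Treml1, a receptor of platelet granules, by 1.61 ± 0.17, Gp1bb, a chain of the von Willebrand factor receptor, by 1.06 ± 0.16, the platelet chemokine Ppbp by 0.99 ± 0.20, and Vwf by 0.72 ± 0.12. With the mean of its probe sets Gp1bb differed by 0.55. The count was 7 with mouse as a block and 2 without blood replicate 2. Camera gave an adjusted p of 1.65e-04 for the list, and an adjusted p = 0.557 with an estimated correlation. Genes of oxidative phosphorylation had a median difference of 0.13, with 36 of 52 members higher in both mice and 0 passing over the list alone. Camera gave them an adjusted p of 0.0049, and an adjusted p = 0.557 with an estimated correlation. The list lost its call without blood replicate 1 (adjusted p = 0.238), without spleen replicate 2 (adjusted p = 0.165) and with quantile normalization (adjusted p = 0.104).

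**Figure D1:**
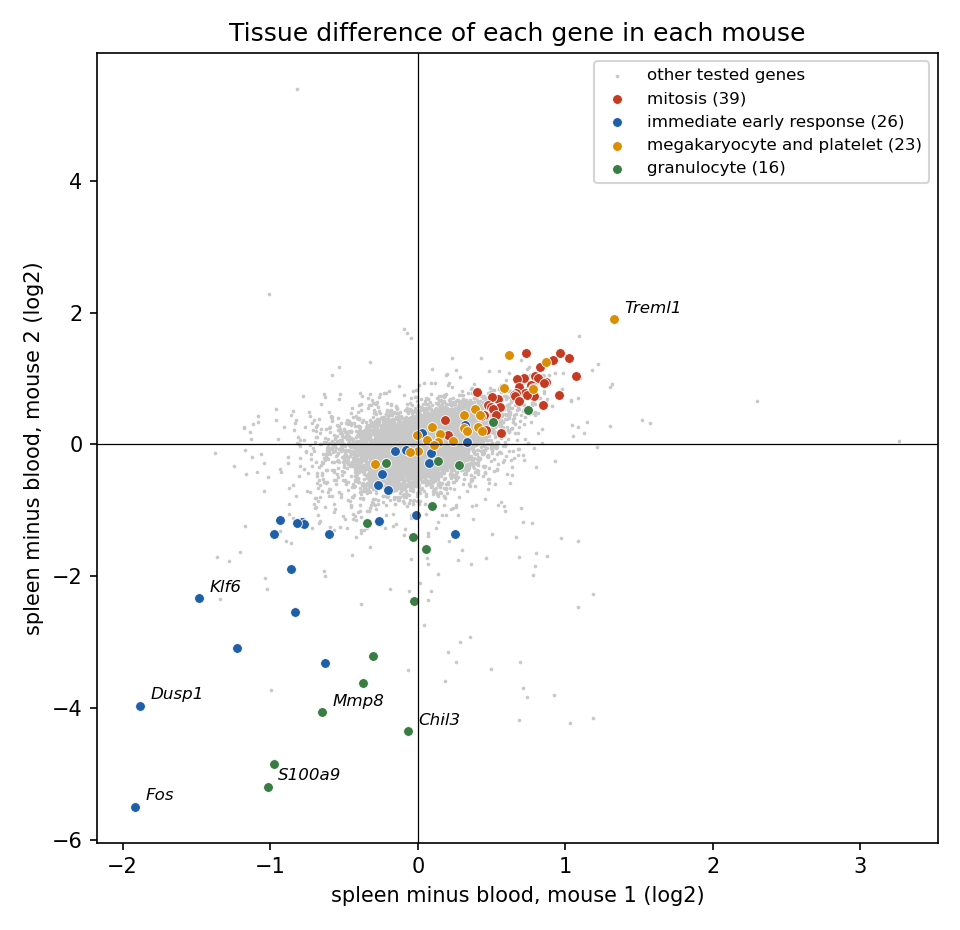
Each point is a tested gene, placed by its log2 difference of spleen minus blood in mouse 1 (horizontal axis) and mouse 2 (vertical axis), with 4 gene lists coloured and the number of tested members in the key. All 39 mitosis genes lie at the upper right, above 0 in both mice, and Fos, Dusp1 and S100a9 lie at the lower left with larger differences in mouse 2.

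Immediate early genes were lower in spleen in both mice for 20 of 26 tested members, with a median difference of -0.43 in mouse 1 and -1.17 in mouse 2. Adjusted over the list alone, 15 fell and 11 did not pass. Fos, a subunit of the AP-1 transcription factor, fell by 3.71 ± 0.75 on the log2 scale, the MAP kinase phosphatase Dusp1 fell by 2.92 ± 0.54, Zfp36, which promotes mRNA decay, fell by 2.16 ± 0.41 and the transcription factor Klf6 fell by 1.91 ± 0.23. Fos had an intensity of 3.26 in spleen of mouse 2, near 0, so the size of its difference rests on the offset, and it was -2.62 with an offset of 64. The list was called at an adjusted p of 6.3e-14, with an adjusted p = 0.557 with an estimated correlation. Camera also called it on the crossed split, at an adjusted p of 7.8e-04 with a median difference of 0.21. The 55 tested markers of granulocytes, macrophages and monocytes, T and NK cells and MHC class II had a median difference of -0.75 in mouse 2. In mouse 1 they went both ways, 28 higher and 27 lower in spleen with a median of 0.03.

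Markers of granulocytes were lower in spleen of mouse 2, with a median difference of -1.50, and their median in mouse 1 was -0.05. Adjusted over the list alone, 5 of 16 passed. S100a9 fell by 3.11 ± 0.91, S100a8 fell by 2.92 ± 0.84 and Mmp8 fell by 2.36 ± 0.70, while Prtn3 rose by 0.63 ± 0.13 and Ctsg by 0.42 ± 0.13. The within-mouse differences in mouse 1 and mouse 2 were -1.02 and -5.20 for S100a9, -0.98 and -4.86 for S100a8 and -0.65 and -4.06 for Mmp8. Without spleen replicate 2 these genes differed by -1.68, -1.60 and -1.56, and without blood replicate 2 Mmp8 differed by -1.45. S100a8 and S100a9 are abundant proteins of mature neutrophils and Mmp8 is a granule collagenase, whereas Prtn3 and Ctsg are proteases made in immature granulocytes. The number of passing genes was 0 with mouse as a block. It was 11 without blood replicate 1, 9 without spleen replicate 1, 0 without blood replicate 2 and 1 without spleen replicate 2. Camera gave an adjusted p of 1.4e-04, and an adjusted p = 0.557 with an estimated correlation. On the crossed split camera gave this list a lower adjusted p, 6.9e-09. The median there was 0.75, with spleen of mouse 1 and blood of mouse 2 on the higher side.

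The other 5 called lists of immune cells and responses had medians below 0 over both mice, by smaller amounts. Camera at the preset correlation also called these 5 on the crossed split, which called 7 lists in all. The crossed adjusted p was 5.4e-09 for macrophages and monocytes and 4.8e-04 for T and NK cells. It was 0.0063 for MHC class II and 0.0150 for the inflammatory list. These 4 lay below the adjusted p for tissue, and that of the interferon list, 0.0042, lay above it. The interferon response list had a median difference of -0.20, with 23 of 34 members lower in both mice, 0 passing over the list alone and an adjusted p of 5.6e-08. The medians were -0.36 for macrophages and monocytes (adjusted p = 0.0211), -0.28 for T and NK cells (adjusted p = 0.0153), -0.15 for dendritic cells and MHC class II (adjusted p = 0.0474) and -0.18 for the inflammatory and NF-kB response (adjusted p = 0.0338). In mouse 1 the medians of the macrophage, T and NK and inflammatory lists were above 0, at 0.16, 0.03 and 0.02. Lower in both mice were 2 of 12 macrophage genes, 5 of 15 T and NK genes, 4 of 12 MHC class II genes and 6 of 17 inflammatory genes, and 0 of any of these lists passed over the list alone. Each of these 5 lists had an adjusted p = 0.557 with an estimated correlation. With mouse as a block, MHC class II (adjusted p = 0.0738) and the inflammatory list (adjusted p = 0.0735) were not called. The macrophage, T and NK, MHC class II and inflammatory lists lost their calls without blood replicate 2 (adjusted p from 0.107 to 0.772) and without spleen replicate 2 (adjusted p from 0.173 to 0.220), and MHC class II also without spleen replicate 1 (adjusted p = 0.0633). With quantile normalization these 4 lists had an adjusted p from 0.0546 to 0.104. With no brightness filter the macrophage list (adjusted p = 0.4997) and the MHC class II list (adjusted p = 0.171) were not called, nor was MHC class II with the mean of all probe sets (adjusted p = 0.0551) or the inflammatory list without markers of other blood cells (adjusted p = 0.0717). Gzma, a granzyme of NK and T cells, differed by 1.03 in mouse 1 and by -4.23 in mouse 2. Mpeg1, a macrophage gene, had intensities of 71.8 and 184 in blood and spleen of mouse 1 and of 708 and 24.7 in mouse 2, and the iron exporter Slc40a1 had 21.9 and 348 in mouse 1 and 119 and 124 in mouse 2. Values below the filter of 106 are dim, and log2 differences that rest on them depend on the offset.

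Lists that were not called were erythroid genes (adjusted p = 0.684), B and plasma cells (0.539), mast cells and basophils (0.349), stroma and endothelium (0.438), hematopoietic progenitors (0.713), the IGF axis and fetal programme (0.0877), heat shock and unfolded protein response (0.722), hypoxia and glycolysis (0.735), cholesterol synthesis (0.382), adhesion and homing (0.121) and ribosomal proteins (0.664). The median of the ribosomal list was below 0 and its mean above 0. Within these lists, adjusted over the list alone, the stem cell factor receptor Kit rose by 0.61 ± 0.12, the erythroid gene Hemgn by 0.72 ± 0.12 and the chemokine receptor Cxcr4, which retains cells in bone marrow, by 0.66 ± 0.14. The kinase-like protein Trib2 fell by 0.52 ± 0.11 and the glucose transporter Slc2a3 fell by 0.68 ± 0.12.

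**Figure D2:**
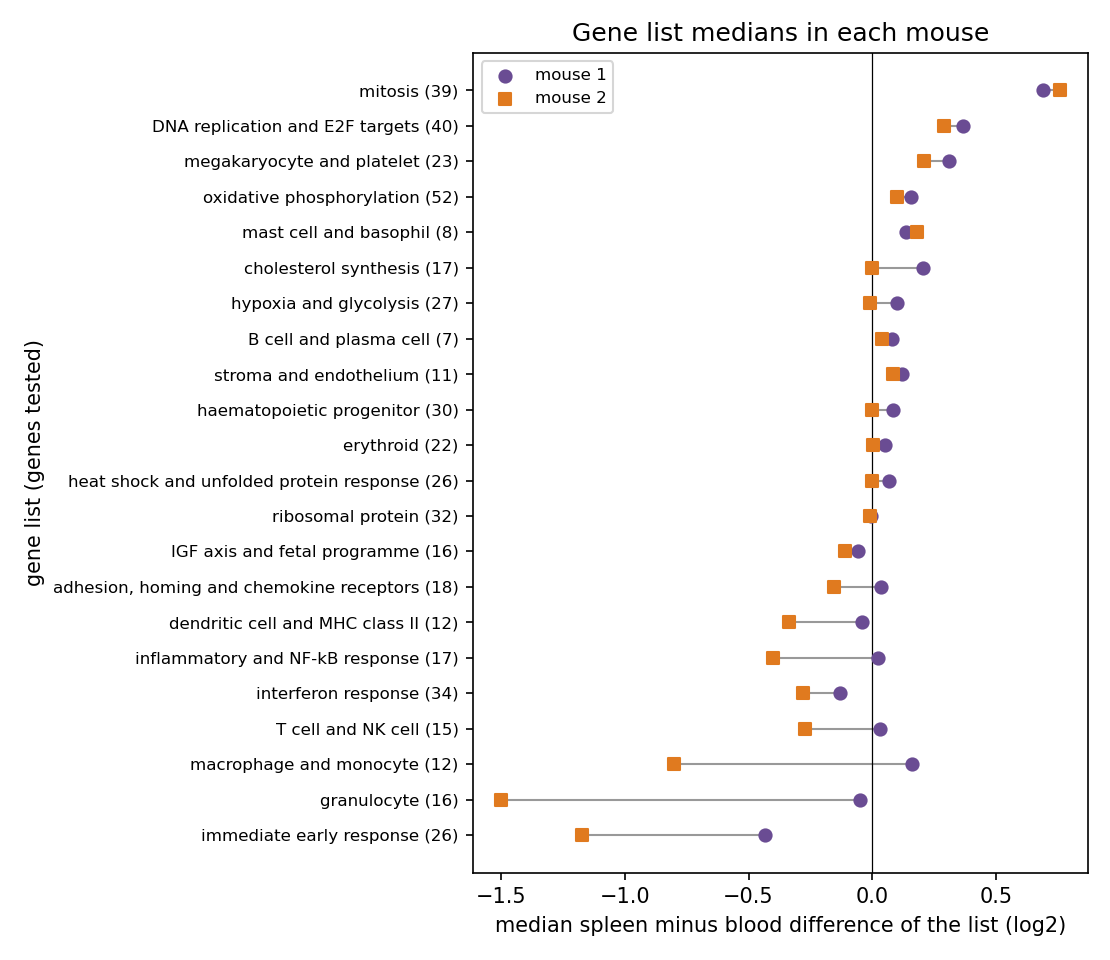
Median log2 difference of spleen minus blood for each of the 22 gene lists, with mouse 1 as circles and mouse 2 as squares. The mitosis list lies at 0.69 and 0.75, and the granulocyte list at -0.05 and -1.50.

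A count without a test gave genes that differed at least 2-fold the same way in both mice. There were 19 such genes, 7 higher and 12 lower in spleen, and another 6 differed at least 2-fold in opposite directions in the mice. Among genes named by the size of their smaller difference, Ahnak, a large membrane scaffold protein, differed by -1.42 ± 0.14, the LIM protein Fhl1 by -1.21 ± 0.12, the kinase Dyrk3 by -1.52 ± 0.16, Tppp3 by -1.53 ± 0.17, the activation antigen Cd69 by -1.85 ± 0.23, the adhesion receptor Adgre5 by -1.53 ± 0.25 and the GTPase Rhob by -1.61 ± 0.27. With the mean of all their probe sets, Ahnak differed by -0.28 and Fhl1 by -0.47. Higher in spleen were Gpr137c at 1.37 ± 0.34, the lipid kinase Pik3c2a at 1.22 ± 0.21, Naaladl2 at 1.15 ± 0.24, the ammonium transporter Rhcg at 1.10 ± 0.20 and Trim59 at 1.04 ± 0.17. Rhcg and Trim59 are not among the 19, with differences of 0.94 and 0.98 in mouse 1. Without blood replicate 2 Gpr137c differed by 0.86. None of these passed over all genes. In mouse 1 alone 58 genes differed at least 2-fold, and in mouse 2 alone 187 did.

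The second comparison described how the 2 animals differed, with 1 animal per side and no test. At least 2-fold differences of the same direction in both tissues were found for 10 genes, 4 higher and 6 lower in mouse 2, while 30 genes differed at least 2-fold in opposite directions in the 2 tissues. The transcript AU015836 had intensities of 931 in blood and 1060 in spleen of mouse 1, and of 41.4 and 34.4 in mouse 2. Lower in mouse 2 were Fcer1a, a chain of the IgE receptor, by -1.25 and -1.67 in blood and spleen, and one probe set of the lipase Mgll, by -1.07 and -1.30. With the mean of its 4 probe sets Mgll differed by -0.0038 over both tissues. Higher in mouse 2 were Tex19.2, by 1.63 and 1.79, the clock gene Per1, by 1.35 and 1.52, Nt5dc2, by 1.28 and 1.39, and Them6, by 1.23 and 1.57.

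**Figure D3:**
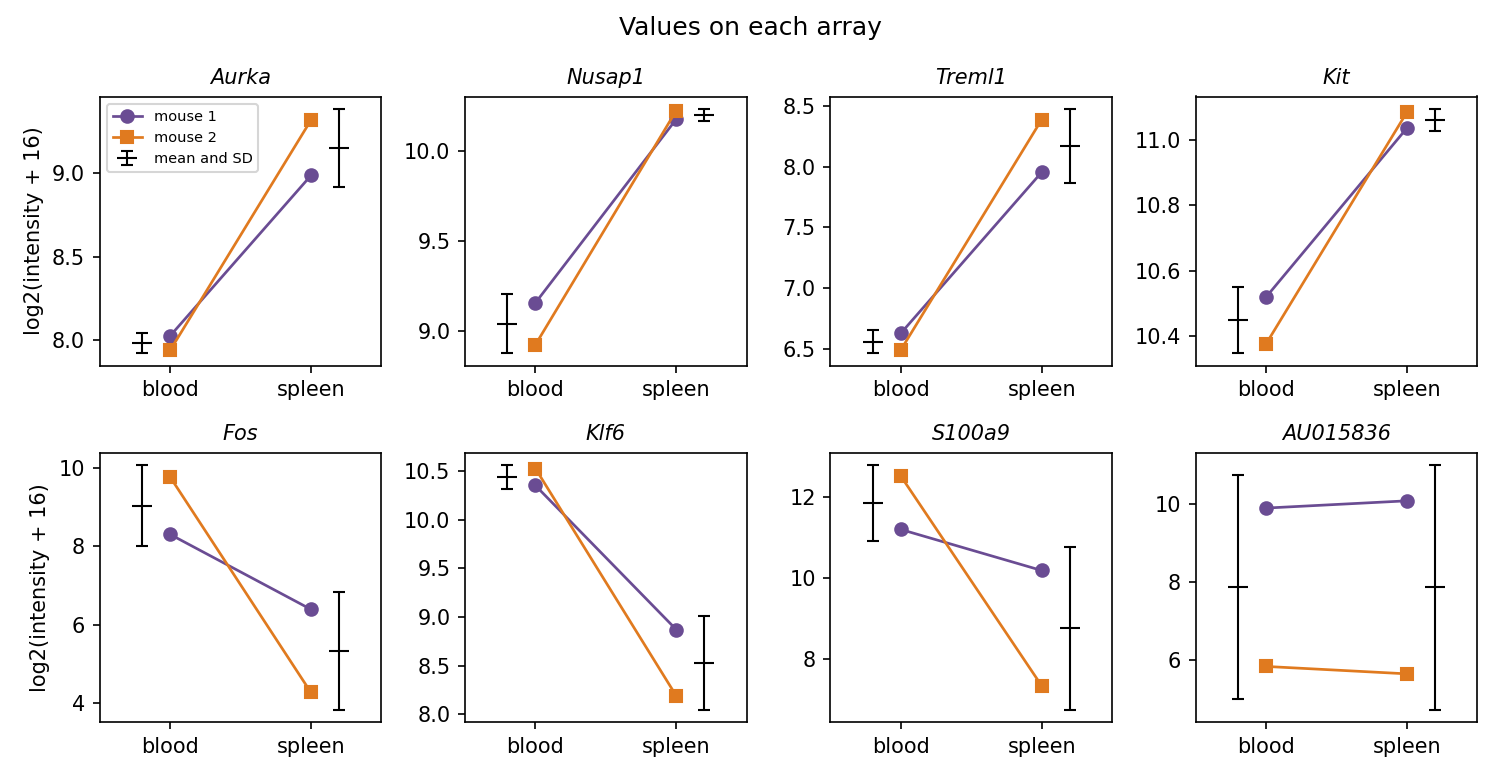
log2(intensity + 16) of 8 genes in blood and spleen, with a line for each mouse and the mean ± SD of the 2 arrays beside each tissue; the vertical axes differ between genes and do not start at 0. Aurka, Nusap1, Treml1 and Kit are higher in spleen of both mice, Fos, Klf6 and S100a9 are lower, and AU015836 differs between the mice.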

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

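The tests in this part were chosen after the values were seen. Among the 11 called gene lists, 3 had median differences of spleen minus blood in opposite directions in the mice: the median of mouse 2 minus that of mouse 1 was -0.96 for macrophages and monocytes, -0.30 for T and NK cells and -0.42 for the inflammatory and NF-kB response. The calls on the crossed split bear on this difference between the mice. No further p-value is given for it, since each tissue of each mouse is 1 array.

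Many markers of mature blood cells stood highest in blood of mouse 2 and lowest in spleen of mouse 2. This held for 11 of 16 tested granulocyte markers, 7 of 12 of macrophages and monocytes, 6 of 15 of T and NK cells and 2 of 12 of dendritic cells and MHC class II. S100a9 had intensities of 2333, 1146, 5862 and 144 in blood and spleen of mouse 1 and blood and spleen of mouse 2, and Gzma had 1338, 2757, 3486 and 171. The sort for GFP should remove cells without the reporter. The median difference of all 11614 tested genes in mouse 2 was 0.0065, so the markers did not move with the genes as a whole. The deposited arrays had like medians, so that value was close to fixed and does not test how they were scaled. With quantile normalization the granulocyte genes passing over the list alone went from 5 to 0. Their median difference over both mice stayed between -0.83 and -0.67 under every scaling, filter and offset. Over the 4 lists, 26 of 55 tested markers had that highest and lowest array. That count restates the pattern and does not bear on whether RNA from other blood cells lies behind it. Of the 55 markers 4 stand on another list and 8 exceeded an intensity of 1000 on average. With 1 array per tissue and mouse, such RNA and a difference between the blasts of the 2 tissues cannot be told apart.

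The probe sets with no gene name, which the comparisons do not use, were counted in the same way, without a test. Of the 2984 of them that were bright enough to be tested, 6 differed at least 2-fold the same way in both mice, 3 higher and 3 lower in spleen, and 1 differed that much in opposite directions.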

How the results depend on the processing

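The mouse 1 count, the list counts under all settings, the list medians and levels under other scalings, and the lists without markers of other blood cells were added after seeing the data. Of the values for single genes, 1112 kept their direction and side of the threshold and 36 newly passed it. These genes were picked for the same direction in both mice and none passed as reported, so keeping both was likely beforehand. Of the list tests 269 kept theirs, 44 lost the call, 2 gained it and 11 changed direction. Calls were gained by adhesion and homing with an array left out and by the IGF axis under another setting (camera, adjusted p = 0.0121). The cause was not tested for the values below, except that fewer genes or arrays entered under the filters and when an array was left out, where the lone array of a tissue was assumed to vary like the others. Genes called over all genes, 0 as reported, were 40 under the stricter filter, 45 with an intensity trend, and from 0 to 20 with each array left out. Of the 45, 11 were mitosis genes, as were 15 of the 40, and 29 genes were called under both. Gene lists called, 11 as reported, were 6 with quantile normalization, 0 with an estimated correlation, 0 with fry, 6 without markers of other blood cells, which removed 4 called lists and ended the call of the inflammatory list, and from 6 to 11 with each array left out. With mouse as a replicate block 9 lists and 0 genes were called, and the blocked count of megakaryocyte genes passing over the list alone was 7, of granulocyte genes 0, of immediate early genes 17, of DNA replication genes 15 and of mitosis genes 36. Among the lists, the pairing ended the calls of MHC class II and the inflammatory list. Genes of other lists were not counted with the block.

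Genes differing at least 2-fold the same way in both mice, 19 as reported, were 42 with no filter, 11 with offset 64, 164 at 1.5-fold, 2 at 3-fold and 58 in mouse 1 alone. Between the mice, 10 as reported, they were 40 with no filter, 1 under the stricter filter, 6 with offset 64, 69 at 1.5-fold and 2 at 3-fold. Over the list alone, granulocyte genes passing were 0 with quantile normalization, no filter, offset 1 and the fit without eBayes, 8 with offset 64, 10 with an intensity trend, 1 with the robust prior and from 0 to 11 with each array left out. Genes of DNA replication were 0 with no filter and without eBayes, 22 with the intensity trend and from 0 to 13 with each array left out. Megakaryocyte genes were 7 with centred arrays and with the mean of probe sets, 0 without eBayes and from 2 to 5 with each array left out. Immediate early genes were 0 without eBayes, and mitosis genes lay between 28 and 38 under every setting.

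Among lists that were not called, the direction changed for hematopoietic progenitors (adjusted p = 0.951) and ribosomal proteins (0.895) with quantile normalization, and for ribosomal proteins with fry (0.875). It also changed for B cells (0.622), mast cells (0.4997) and stroma (0.612) with no filter, and for stroma under the stricter filter (0.957). With each array left out, adjusted p ranged from 0.265 to 0.801 for heat shock, from 0.552 to 0.924 for hypoxia and from 0.372 to 0.907 for ribosomal proteins. Rps6 had a difference of -0.0085 with the mean of its probe sets. Centring the arrays moved the split of genes at an unadjusted p under 0.05 from 943 higher and 500 lower to 1310 and 354 and quantile normalization to 765 and 602, and without spleen replicate 1 it was 768 and 772. Centring came with a median shift of all genes of 0.072 instead of 0.029. Signal over background limits dim genes: the filter at an intensity of 106 leaves 11614 of 18193 genes.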

Other observations

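The tests for mitosis, immediate early genes and Per1 were chosen after the values were seen. Several genes outside the main lists passed limma's test with an intensity trend, those named here each at an adjusted p of 0.049. The lamin Lmna (-0.76), the annexin partner S100a10 (-0.92), the LIM protein Crip1 (-0.83) and the phosphodiesterase Pde4b (-1.18) were lower in spleen, and the chaperone Canx (0.73) and the desaturase Scd2 (0.73) were higher. With the constant prior none of them passed.

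Immediate early genes were lower in spleen in both mice. RNA from other blood cells cannot be told apart from a change in the blasts in either mouse. The median of the list differed from that of their markers by -0.46 in mouse 1 (permutation test, p = 3.0e-05). That test shuffles genes as if independent, within 1 pair of arrays. The markers went both ways there with an SD of 0.66, and S100a9 (-1.02) and S100a8 (-0.98) were lower too. In mouse 2 the gap was -0.42 (permutation test, p = 0.42) and the markers were lower as well. Handling may also differ between blood and spleen, and with a median of -0.85 in the same direction in both mice it cannot be told apart from tissue. A biological difference of blasts between the tissues stays open and untested.

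Mitosis genes were higher in spleen in both mice. A lower share of leukemic cells in blood as the sole cause is argued against. In mouse 1 the mitosis median lay 0.60 above that of the progenitor list, and in mouse 2 0.76 above it. Each gap was more than the SD of the progenitor list, 0.22 in both mice. Permutation tests with 100000 draws gave p = 1e-05 in each, the smallest they can give. They shuffle genes as if independent, within 1 pair of arrays per mouse, for a list picked from the same data. A partly lower share stays open, since megakaryocyte and platelet genes were also higher in spleen, with a median difference of 0.27. The mitosis median was at least 0.69 with quantile normalization or centring. The deposited arrays had like medians, so rescaling could move it little, and its staying high does not test how they were scaled. That blasts in the spleen divide more is a hypothesis found and examined on the same data; dividing cells of other kinds in the spleen were not tested.

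Per1 was higher in mouse 2 in both tissues, which may come from time of day at collection or from a glucocorticoid response. Of 8 other tested clock genes, 0 differed at least 1.5-fold the same way in both tissues, but 6 were lower in mouse 2 in both by less, so time of day cannot be told apart from another difference between the 2 animals, with 1 animal per side. A glucocorticoid response cannot be told apart from another difference between the animals either. Of 10 other induced genes 0 were higher by 1.5-fold in mouse 2 in both tissues. By less, 4 were higher in both tissues and 1 was lower in both.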
